A study of Homo sapiens with 8 samples.

How the data were processed

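The material was primary human aortic endothelial cells, the cells that line the aorta, cultured under laminar shear stress and profiled by droplet single-cell RNA sequencing. Per the labels, physiologic flow was a shear stress of 30 dyn/cm2 and altered flow 2.5 dyn/cm2. Each was kept for 72 h. In the drug arms rapamycin, an inhibitor of the kinase mTOR, or paclitaxel, which stabilises microtubules, was added after 24 h of flow and the cells were harvested 48 h later. The 8 libraries were 2 controls under each flow and 1 library of each drug under each flow. Nothing in the labels says that libraries of a group came from separate cultures or donors. Every p-value thus measures only the spread between these libraries, which may be technical or hold true differences between conditions.

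The values were counts per gene and cell barcode, which the authors deposited in 2 formats. The first control of each flow and both rapamycin libraries came as dense tables of genes by cells, called single-table libraries here. The second control of each flow and both paclitaxel libraries came as sparse matrices with separate gene and barcode lists, called sparse-matrix libraries here. Per the labels' protocols each transcript was tagged with a cell barcode and a molecular identifier, but no header or label says whether the deposited counts were collapsed to molecules, so they are called counts. Per the submitters' processing notes the reads were converted with bcl2fastq (version not given) and the genome build was hg19. The aligner, the counting program, the annotation and the cell filter were not given in the sources used here, nor whether both formats were counted against the same annotation. The notes name hg19 for all 8 libraries, but the files hold no coordinates to check it, and the gene names of the formats differ in part, so a format difference in a gene's level can also come from its annotation. Every single table held 6000 barcodes, whereas the sparse matrices held 846, 153, 399 and 229 barcodes for the physiologic control, altered control, physiologic paclitaxel and altered paclitaxel libraries. No barcode of a sparse matrix had fewer than 2049 counts, so the formats also differed in how shallow a barcode could be and still be listed.

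Genes were joined by symbol. The sparse matrices shared a list of 33538 genes. Symbols of the single tables that did not occur there were looked up among older and current symbols in a RefSeq gene table used for names only. The symbols left unmatched carried 4.82% to 6.76% of the counts of a single table, and symbols that pointed to more than 1 gene carried at most 0.0905% of the counts of a sparse matrix. The single tables listed only genes with at least 1 count. The tests started from the 18017 genes of the feature list that at least 1 single table also listed. Of these, 4030 were missing from at least 1 other single table and were set to 0 there. XIST and Y-linked genes, 102 in the feature list, were left out of every test, and in a check for mixed-up samples 0 libraries did not match the others of their own deposit format. That check did not compare the formats with each other, and whether they came from the same donor or culture is not given in the sources used here. Genes are named by symbol, and no positions are printed because no annotation of the authors' build was used here. Counts of near-identical gene copies, such as tubulin, metallothionein and ribosomal protein genes, are uncertain where the authors' counting could split reads between copies.

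Cells with at least 500 counts and at most 25% of counts from the mitochondrial genes listed in their own file were kept. This left 3387, 4978, 5095 and 3385 cells of the physiologic control, altered control, physiologic rapamycin and altered rapamycin single tables, and every barcode of the sparse matrices. No doublet caller was run and no doublets were removed. Raw counts of the kept cells were summed per library, because cells are not replicates. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors between 0.958 and 1.05, Benjamini-Hochberg (BH) adjusted p below 0.05). The additive model held the condition, with 4 levels (the control of each format, rapamycin, paclitaxel), and flow, with 3 residual degrees of freedom. It gave the flow effect over 8 libraries, the rapamycin and paclitaxel effects, each against the control of its own format, and the difference of the drug effects. Each condition held 1 library per flow, so the residual spread of this model is the disagreement of the flow change between conditions. That spread includes any true differences of the flow change by drug or format. The control libraries alone were tested 2 against 2 with no block. A flow by drug interaction was added to the additive model for each drug, which left 2 residual degrees of freedom. Log2 fold changes carry a standard error computed as their size divided by the square root of the F statistic. CPM are counts of a gene scaled to a common library size.

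The groups of controls share replicate numbers, and each number is also a deposit format. The deviations of the 2 controls of a number from their group means were correlated across genes with r = 0.727, so the number pairs the controls, and since the labels give the formats, the pairing marks the format. The fit with the number as a block is printed beside the control result.

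The 29 gene lists were fixed before the data were examined. They held flow-protective genes, low-flow inflammatory genes, YAP/TAZ targets, NRF2 targets, BMP and Notch targets, endothelial identity, arterial, mesenchymal transition, tip cell and angiogenesis genes, G1/S genes, G2/M genes, p53 targets, tubulins, cholesterol and fatty acid synthesis, ATF4 and amino acid genes, ribosomal proteins, translation factors, lysosome and autophagy, glycolysis and hypoxia, endoplasmic reticulum (ER) stress, interferon genes, secreted senescence genes, mitochondrially encoded genes, immediate early and heat shock genes, metallothioneins and nuclear oxidative phosphorylation genes. Markers of smooth muscle, of fibroblasts and of blood cells stood for other cells a primary culture could hold. Lists share members (HEY1, for example, is among both the arterial and the BMP and Notch genes). They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with BH adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. No list called by camera in the flow, rapamycin, paclitaxel or drug difference comparison was called with an estimated correlation, and fry called 1 list, the YAP/TAZ targets, in the flow comparison. Counts adjusted over the list alone use BH over the members of that list.

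The named genes were chosen by a rule also fixed before the data were examined. For the flow, rapamycin and paclitaxel effects these are the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 20 CPM and the same sign in every pair of libraries. Where a direction had fewer than 10, the genes with the smallest p of that sign, CPM and sign agreement filled up and are given as not past the threshold. Up to 4 members of each list with the smallest p could be named besides. For the control-only, interaction and drug difference comparisons the 5 genes with the smallest p in each direction are named. A few genes that the rule takes are not reported here. For 1 library against 1, the 5 largest CPM ratios each way among genes with at least 100 counts over both libraries and at least 10 in each are named, computed with a pseudocount of 0.5 CPM.

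With 1 library per drug and flow, no test was made of the drug within a flow. CPM of both libraries are given with exact Poisson 95% intervals, which cover counting error only, as do the binomial intervals below. A list's median ratio is set beside 10000 random lists of the same size matched on mean expression over 20 bins. Cells were scored for 5 marker sets fixed beforehand (endothelial, smooth muscle, fibroblast, leukocyte and cycling), and a cell counted for a class with at least 2 distinct markers seen. Each cell was thinned to 1000 counts and shallower cells were left out. Shares have exact Clopper-Pearson 95% intervals. Cells were clustered separately within each format with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5) in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

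The tests were run on simulated counts drawn from the real means and library sizes, with 200 genes changed. In the flow simulation over 12361 genes, 44.8% of the genes changed 2-fold and 88.7% of those changed 4-fold were recovered, with 13 unchanged genes called. The shares recovered were 15.2% and 79.4% for rapamycin (12441 genes) and 9.00% and 68.0% for paclitaxel (12453 genes), with 13 and 2 unchanged genes called. In the control-only simulation 0 of 96 genes changed 2-fold and 0 of 98 changed 4-fold were recovered, and for the flow by rapamycin interaction 0 of 99 and 8 of 99, with 0 and 5 unchanged genes called. A list of 25 genes raised by 0.5 (log2) was called in each of the flow, rapamycin and paclitaxel simulations, and 0 of 40 unchanged lists were. The draw used means and library sizes, not the correlation between genes, so it cannot tell how often lists of correlated genes are falsely called. In the flow comparison the estimated correlation ran from -0.0405 (YAP/TAZ targets) to 0.857 (mitochondrially encoded genes). It was 0.447 for G2/M, 0.619 for ribosomal protein and 0.713 for cholesterol synthesis genes. In the simulated 1-against-1 comparison the raised list stood at percentile 100.0, and 10 of 200 unchanged lists fell outside the middle 95%, a number of lists chosen after seeing the data.

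Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no gene filter, all barcodes, a stricter cell filter (1000 counts, 10% mitochondrial), thinning of all libraries to the smallest total, leaving out mitochondrial and ribosomal protein genes, each format alone, the format left out of the model, the block, leaving out each library in turn, the other control for the drug pairs, unthinned cells and Leiden resolution 1. A separate flow effect in each format, a minimum of 2000 counts per cell and the median size of the log2 ratio as a summary of the 1-against-1 pairs were chosen after seeing the data. The fit of a flow by format difference, with 2 residual degrees of freedom, was also chosen then. Genomic spans for a test of gene length came from the GENCODE annotation of another genome build and were used as lengths only.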

Results

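Single-cell transcript counts were compared between human aortic endothelial cells under physiologic and altered flow, without drug, with rapamycin or with paclitaxel. The question was how the flow condition changes the endothelial transcriptome and how each drug changes it under each flow. Total counts were 21922781 and 28934989 in the single-table physiologic and altered controls and 24564567 and 21247774 in the physiologic and altered rapamycin libraries. The sparse-matrix libraries were shallower in total, with 6547049 and 3627735 counts in the controls and 3879022 and 3704334 with paclitaxel. They were deeper per cell, with medians of 5988 to 12629 counts against 1487 to 2022 in the kept cells of the single tables. The mitochondrial genes that each file listed took 4.52% to 5.82% of the counts in the single tables and 0.305% to 0.50% in the sparse matrices. The formats did not list the same genes, so these shares are not like for like. Over the joined genes the clusters of cells held 1.40% to 2.62% mitochondrial counts in the single tables and 0.296% to 0.450% in the sparse matrices.

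Altered flow raised EDN1, which encodes the vasoconstrictor endothelin, by 3.21 ± 0.14 on the log2 scale (SE, n = 4 pairs of libraries, edgeR BH-adjusted p = 0.000539). Its level was 80.9 to 103.4 CPM in the 4 physiologic libraries and 784 to 976 CPM in the 4 altered ones. SELP, the adhesion receptor P-selectin that binds leukocytes, rose by 3.09 ± 0.54, and BMP4, a growth factor of the TGF-beta family, by 3.09 ± 0.29. ALDH1A1, an enzyme that makes retinoic acid, rose by 5.97 ± 0.75. STC1, a secreted stanniocalcin, fell by 3.92 ± 0.17 (edgeR BH-adjusted p = 0.000539). PI16, a peptidase inhibitor, fell by 7.68 ± 1.12, from 32.2 to 596 CPM under physiologic flow to 0.46 to 3.45 CPM under altered flow. CCN3, a matricellular protein, fell by 3.77 ± 0.39, CYP1B1, a cytochrome P450, fell by 3.40 ± 0.23, and IGFBP5, which binds insulin-like growth factors, fell by 4.62 ± 0.88. The edgeR test called 509 of 12596 genes at a BH-adjusted p below 0.05, 251 higher and 258 lower. Of these, 170 and 152 changed at least 2-fold. The other named risers were the matrix genes CCDC80 (2.94 ± 0.35), THBS1 (2.70 ± 0.41) and BGN (2.66 ± 0.49), the guidance factor SEMA5A (2.87 ± 0.56), the Notch effector HEY1 (2.46 ± 0.32) and LINC01013 (2.41 ± 0.39). SELP and SEMA5A each had 0 counts in 1 library. The other named fallers were LMO7 (-2.91 ± 0.33), the protocadherin PCDH12 (-2.72 ± 0.32), HSPA12B (-2.57 ± 0.33), the noncoding LINC00520 (-2.52 ± 0.22) and the protease ADAMTS4 (-2.49 ± 0.22). The edgeR BH-adjusted p of the 20 named genes lay between 0.000539 and 0.0411.

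**Figure D1:**
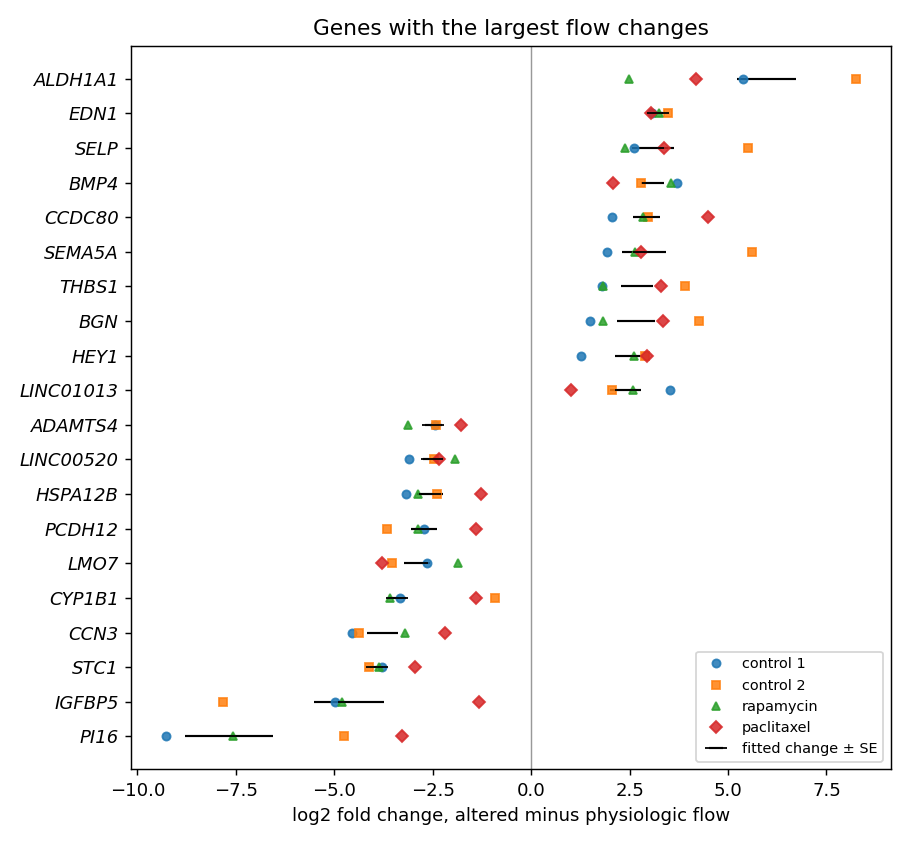
Log2 fold change (altered minus physiologic flow) of the 20 named genes of the flow comparison, with 1 point for each of the 4 pairs of libraries and a line for the fitted change ± SE. All 4 points of each gene lie on the same side of 0, as the rule for naming them requires, and the fitted changes run from -7.68 for PI16 to 5.97 for ALDH1A1.

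The flow effect over 8 libraries was also fitted within each format. The 4 single-table libraries alone called 2068 genes (974 higher, 1094 lower), 505 of them among the 509. The 4 sparse-matrix libraries alone called 2053 (1273 higher, 780 lower), 394 of them among the 509. These fits had fewer residual degrees of freedom than the fit over 8 libraries. Their spread is only the disagreement between a control pair and a drug pair, so the larger counts are not stronger evidence. A fit with a separate flow effect in each format, chosen after seeing the data, called 3009 genes for the mean flow effect, 498 of them among the 509. The fit without any format term called 4 genes, EDN1, EFEMP1, QPCT and STC1, of which EFEMP1 and QPCT are named after their values were seen. Leaving out the physiologic or the altered single-table control left 226 and 229 called genes, and leaving out those of the sparse-matrix format left 46 and 44. Leaving out physiologic or altered rapamycin left 53 and 54, and leaving out physiologic or altered paclitaxel gave 537 and 522. Across the 7356 genes of the correlation, which are not independent replicates, the flow changes of pairs in the same format had Pearson r = 0.795 (Spearman 0.635, control with rapamycin) and 0.780 (0.690, control with paclitaxel), and those of the 2 control pairs 0.385 (0.244). Between formats the other values were 0.160 (0.0939) for the single-table control with paclitaxel, 0.302 (0.189) for rapamycin with paclitaxel and 0.533 (0.405) for the sparse-matrix control with rapamycin.

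Among the flow-protective genes, which laminar flow is known to induce, 9 of 19 tested members fell and 0 rose (1 rose and 13 fell adjusted over the list alone). The list's median log2 fold change was -0.85 (camera BH-adjusted p = 2.16e-06, adjusted p = 0.545 with an estimated correlation). They included NOS3, the endothelial nitric oxide synthase (-1.26 ± 0.13), the sialomucin PODXL (-1.15 ± 0.12) and the scaffold NHERF2 (-1.61 ± 0.22). Among low-flow inflammatory genes 2 of 21 rose (7 rose and 1 fell adjusted over the list alone), BMP4 and the coagulation initiator F3 (1.43 ± 0.29). The list's median was 0.57 (camera BH-adjusted p = 0.0140, adjusted p = 0.545 with an estimated correlation). In the single-table control pair alone, with no test, the inflammatory median was 0.15 (8 of 15 genes positive, percentile 78.6), against 0.53 to 1.38 in the other 3 pairs. The chemokines CCL2 (2.69 ± 0.64) and CXCL8 (0.95 ± 0.22) had edgeR BH-adjusted p of 0.0700 and 0.0677. Among YAP/TAZ targets 5 of 21 rose (8 adjusted over the list alone), among them EDN1, CCN2 (2.06 ± 0.26), CCN1 (1.23 ± 0.17) and CRIM1 (1.12 ± 0.13). The median of these targets was 0.40 (camera BH-adjusted p = 0.00310, adjusted p = 0.545 with an estimated correlation, fry adjusted p = 0.0154).

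BMP and Notch targets rose as a list (3 of 10 members, 4 adjusted over the list alone, median 0.88, camera BH-adjusted p = 0.0140), with ID2 (1.46 ± 0.22) and ID3 (1.39 ± 0.19), inhibitors of DNA binding, beside HEY1. Of 17 arterial genes 3 rose (5 rose and 1 fell adjusted over the list alone, median 1.00, camera BH-adjusted p = 0.000540), among them the kinase BMX (1.61 ± 0.33) and the elastic fibre gene FBLN5 (1.28 ± 0.22). Of 28 mesenchymal transition genes 7 rose (9 adjusted over the list alone, median 0.49, camera BH-adjusted p = 0.000771), including the actin-binding TAGLN (2.24 ± 0.33), the matrix gene POSTN (2.07 ± 0.32) and the transcription factor SNAI1 (1.35 ± 0.17). Of 24 tip cell and angiogenesis genes 1 rose (4 adjusted over the list alone, median 0.47, camera BH-adjusted p = 0.00641), the vasodilator peptide gene ADM (1.68 ± 0.28). These calls were lost with an estimated correlation, at adjusted p = 0.545 for each of the 4 lists. Without physiologic or altered rapamycin the BMP and Notch list of the flow comparison was no longer called (camera BH-adjusted p = 0.0797 and 0.0802). In the single-table control pair, with no test, its median was 0.01 (5 of 10 genes positive, percentile 43.6 among matched random lists) and that of the arterial list 0.00 (9 of 17, percentile 39.2), against 0.66 to 0.97 and 0.64 to 0.87 in the other 3 pairs. In the fit of the control libraries alone the BMP and Notch list had a median of -0.03 and a mean of 0.42, with 4 of 10 members positive, and was not called (camera BH-adjusted p = 0.0978).

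As lists, cell cycle genes rose with altered flow over the 8 libraries, but their medians lay below 0 in the paclitaxel pair. Of 50 G2/M genes 2 rose, HJURP (2.12 ± 0.38) and KIF2C (2.06 ± 0.42), which act at the centromere (25 rose adjusted over the list alone). Their median was 1.31 (camera BH-adjusted p = 1.59e-08, adjusted p = 0.564 with an estimated correlation). Of 42 G1/S genes 2 rose, the replication factor GINS2 (2.55 ± 0.33) and the histone chaperone NASP (0.95 ± 0.19) (3 adjusted over the list alone). Their median was 0.56 (camera BH-adjusted p = 0.000984, adjusted p = 0.587 with an estimated correlation). Taken pair by pair, with no test, the G2/M median was -0.11 with paclitaxel (5 of 15 genes positive, percentile 53.6 among matched random lists). It was 0.48 to 1.26 in the other 3 pairs, over 30 to 48 genes. The G1/S median was -0.17 with paclitaxel (5 of 15 positive, percentile 37.5) and 0.42 to 0.52 in the others, over 22 to 39 genes. These medians thus rest on differing members of the lists. The flow by paclitaxel interaction was negative for 39 of 50 G2/M and 35 of 42 G1/S genes, with camera BH-adjusted p of 0.00166 and 8.55e-06 and adjusted p of 0.878 and 0.567 with an estimated correlation. The flow by rapamycin interaction was negative for the G2/M list (-0.55, camera BH-adjusted p = 5.14e-05, adjusted p = 0.891 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell, with 5 of 29 lower and 0 higher (20 lower adjusted over the list alone). Their median was -0.68 (camera BH-adjusted p = 2.42e-10, adjusted p = 0.545 with an estimated correlation). They included the enzymes CYP51A1 (-1.35 ± 0.22), HMGCS1 (-1.11 ± 0.19) and FADS2 (-1.01 ± 0.19). Of 82 ribosomal protein genes 0 passed the edgeR test, over all genes or adjusted over the list alone. Positive values stood in 79 of them, and the list rose by a median of 0.45 (camera BH-adjusted p = 2.17e-10, adjusted p = 0.587 with an estimated correlation). In the single-table control pair alone the ribosomal protein median was 0.03 (44 of 80 genes positive, percentile 79.2), against 0.27 to 0.84 in the other 3 pairs. RPL37 stood at 0.59 ± 0.16 (edgeR BH-adjusted p = 0.0936). Of 18 translation factors 0 passed (1 rose adjusted over the list alone), and the nucleolar NPM1 stood at 0.61 ± 0.13 (edgeR BH-adjusted p = 0.0501). The list's median was 0.27 (camera BH-adjusted p = 0.00374, adjusted p = 0.587 with an estimated correlation). More members passed with a separate flow effect in each format, chosen after seeing the data. There edgeR called 51 of 82 ribosomal protein genes higher (62 adjusted over the list alone), 6 of 18 translation factors (8), 29 of 50 G2/M genes (36) and 13 of 42 G1/S genes (15), with 1 G1/S gene lower, and 23 of 29 cholesterol synthesis genes lower (25).

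In the flow comparison within single tables, camera no longer called the low-flow inflammatory (BH-adjusted p = 0.224), arterial (0.0507), translation factor (0.308) and tip cell lists (0.0920), and within sparse matrices it no longer called the G1/S list (0.302). The other 7 of the 12 called lists were called in each format alone. With a separate flow effect in each format camera also called NRF2 targets (median -0.17) and mitochondrially encoded genes (0.22), each with a BH-adjusted p of 0.0384 and an adjusted p of 0.655 with an estimated correlation. Ribosomal protein genes took 4.29% and 4.58% of the counts in the physiologic and altered single-table controls, 5.01% and 5.90% with rapamycin, 3.84% and 6.31% in the sparse-matrix controls and 4.33% and 6.05% with paclitaxel.

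The remaining lists were not called in the flow comparison, and some held single genes that changed in opposite directions. Of 24 interferon genes (median -0.16, camera BH-adjusted p = 0.146, 1 rose and 2 fell adjusted over the list alone) the antiviral OAS2 (-2.05 ± 0.30) and OAS1 (-1.45 ± 0.25) fell. Of 24 endothelial identity genes (median -0.07, 0.335, 2 rose and 5 fell adjusted over the list alone) the lectin CLEC14A rose (1.48 ± 0.25) and the angiopoietin receptor TEK (-0.88 ± 0.17) and NOS3 fell. Of 24 secreted senescence genes (median -0.16, 0.0667) 1 rose and 7 fell (4 and 9 adjusted over the list alone), and among those that fell were IGFBP5, STC1, IGFBP6 (-2.0 ± 0.31), the collagenase MMP1 (-2.25 ± 0.39) and the plasminogen activator PLAT (-1.11 ± 0.17), which are also made by cells that are not senescent. Of 25 p53 targets (median -0.06, 0.577, 3 rose and 2 fell adjusted over the list alone) PLK2 rose (0.62 ± 0.12) and FAS (-0.95 ± 0.16) and CDKN1A (-0.62 ± 0.11) fell. Of 27 glycolysis and hypoxia genes (median -0.15, 0.131, 1 rose and 6 fell adjusted over the list alone) ADM rose and NDRG1 fell (-1.32 ± 0.12). Of 22 immediate early and heat shock genes (median 0.07, 0.461, 5 rose and 1 fell adjusted over the list alone) IER3 rose (1.66 ± 0.20) and IER5 fell (-1.27 ± 0.22). Camera BH-adjusted p was 0.0585 for NRF2 targets (median -0.18), 0.0916 for mitochondrially encoded genes (0.21), 0.177 for smooth muscle markers (-0.37), 0.192 for oxidative phosphorylation (0.16) and 0.242 for ATF4 and amino acid genes (0.13). It was 0.555 for fibroblast markers (-0.64), 0.729 for tubulins (-0.02) and for metallothioneins (0.50), 0.815 for lysosome and autophagy (0.00) and 0.864 for ER stress (0.02). In these 10 lists, 1 fibroblast marker, PI16, fell over all genes and adjusted over the list alone, and 1 metallothionein rose and 1 fell adjusted over the list alone. The blood cell list had too few tested genes for a list test, and of these CD68, a lysosomal protein of macrophages that other cells also express, fell by 0.92 ± 0.16 (edgeR BH-adjusted p = 0.0313).

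The 4 control libraries alone asked for the flow effect without drug. The genes with the smallest p were EDN1 (3.27 ± 0.33), the channel subunit KCNMB4 (3.60 ± 0.46), the TIE2 ligand ANGPT2 (3.29 ± 0.44), BMP4 (3.22 ± 0.43) and the matrix gene EFEMP1 (2.33 ± 0.34) on the positive side. On the negative side were CCN3 (-4.55 ± 0.51), STC1 (-3.99 ± 0.49), QPCT (-2.09 ± 0.26), ADAMTS4 (-2.44 ± 0.33) and COL17A1 (-2.84 ± 0.45). None of the 12243 genes passed (edgeR, 0 genes, smallest BH-adjusted p = 1.00, n = 2 libraries per flow). An unadjusted p below 0.05 was found for 444, where chance gives 612.15, and DESeq2 called 86 (39 higher, 47 lower). With the replicate number, which is also the format, as a block, edgeR called 2 genes, ALDH1A1 at 8.10 ± 0.48 and CCN3 at -4.60 ± 0.24, each with a BH-adjusted p of 0.0327. ALDH1A1 is named here for this call, after its values were seen. Camera called 11 lists in the control libraries alone, on the fit without the block. That fit leaves out the pairing of the controls, so the shift between formats enters its spread. Higher were G2/M (median 1.88, BH-adjusted p = 8.75e-26), G1/S (0.78, 2.66e-10), ribosomal protein (0.49, 1.08e-06), mesenchymal transition (0.32, 0.00261), ATF4 and amino acid (0.37, 0.00329), YAP/TAZ (0.29, 0.00668), tip cell (0.30, 0.0156) and arterial genes (0.19, 0.0400). Lower were flow-protective (-1.19, 3.1e-08), cholesterol synthesis (-0.67, 2.3e-07) and interferon genes (-0.37, 0.00835). With an estimated correlation the adjusted p was 0.634 for the arterial, 0.528 for the ribosomal protein and 0.453 for each of the other 9 lists. Adjusted over the list alone 6 flow-protective genes were lower, 1 YAP/TAZ target and 1 tip cell gene were higher and 0 members of the others passed.

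Rapamycin was compared with the control of its own format over both flows. Genes of protein folding in the ER fell as a list, with a median of -0.54 over 20 genes (camera BH-adjusted p = 1.42e-10, adjusted p = 0.609 with an estimated correlation, 0 called over all genes and 10 lower adjusted over the list alone). Its chaperones HSPA5, HSP90B1 and CALR stood at -1.34 ± 0.21, -1.06 ± 0.22 and -1.07 ± 0.20, and the disulfide isomerase PDIA4 at -0.81 ± 0.18 (SE, n = 2 libraries against 2). G2/M genes fell, with a median of -0.88 over 50 genes (camera BH-adjusted p = 2.7e-09, adjusted p = 0.774 with an estimated correlation, 2 lower adjusted over the list alone). The cyclin CCNB1 stood at -1.62 ± 0.26 and CDC20, an activator of the anaphase-promoting complex, at -2.65 ± 0.52. The 18 translation factors all had positive values and rose by a median of 0.35 (camera BH-adjusted p = 8.62e-08, adjusted p = 0.609 with an estimated correlation), with the elongation factor EEF2 at 0.64 ± 0.22. Ribosomal protein genes rose by a median of 0.33, with 72 of 82 positive and RPL37 at 0.96 ± 0.22 (camera BH-adjusted p = 4.23e-10, adjusted p = 0.774 with an estimated correlation). Adjusted over the list alone 0 translation factors and 0 ribosomal protein genes passed. With a separate flow effect in each format, chosen after seeing the data, 9 and 25 were higher adjusted over the list alone, 24 G2/M genes were lower, and 13 ER stress genes were lower and 1 higher.

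No single gene of 12596 passed for rapamycin (edgeR, 0 genes, 712 at an unadjusted p below 0.05 where chance gives 629.8), and DESeq2 called 35 (17 higher, 18 lower). CYP1B1 had the smallest edgeR BH-adjusted p, 0.280, at -2.34 ± 0.23. On the negative side followed STEAP1 (-1.21), SNRNP25 (-0.97), the transferrin receptor TFRC (-0.87 ± 0.16), the serine synthesis enzyme PSAT1 (-1.78 ± 0.34), DDIT4, an inhibitor of mTOR signalling (-1.21 ± 0.24), and AK3 (-0.77). On the positive side stood STC1 (1.25 ± 0.19), NOB1 (0.82 ± 0.13), which acts in ribosome assembly, CEP135 (0.92 ± 0.16), NDRG1 (0.92 ± 0.16), UBXN1 (0.79 ± 0.15), the scaffold AKAP12 (1.28 ± 0.25), SYF2 (0.78), SIGIRR (0.86), NOA1 (0.90) and ABRAXAS1 (1.03). With a separate flow effect in each format, chosen after seeing the data, edgeR called 89 genes for rapamycin (39 higher, 50 lower), among them CYP1B1 (-2.33 ± 0.14, BH-adjusted p = 0.000785) and STC1 (1.25, BH-adjusted p = 0.0399).

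The other lists called by camera for rapamycin were lower for cholesterol synthesis (median -0.29, 27 of 29 negative, BH-adjusted p = 0.000112), fibroblast markers (-1.01, 6.45e-05), p53 targets (-0.26, 0.00228), low-flow inflammatory genes (-0.49, 0.00280), ATF4 and amino acid genes (-0.21, 0.00378) and arterial genes (-0.36, 0.00469). The fibroblast list rested on 5 tested genes of 12, and 1 of these had 0 counts in a compared group. Camera called higher values for tubulins (median 0.28, BH-adjusted p = 0.0406). Among their members were COL3A1, a fibrillar collagen (-2.41 ± 0.56), the chemokines CCL2 (-2.38 ± 0.82) and CXCL1 (-1.63 ± 0.57), and TUBB (0.65 ± 0.22), none past the edgeR test. The inflammatory cytokine gene IL1A, at 0 counts in 2 libraries, stood at -2.90 ± 0.45. The numbers of members called adjusted over the list alone were 2 lower for fibroblast markers, 1 lower for inflammatory genes, 2 lower for ATF4 and amino acid genes and 0 for the others. With an estimated correlation the adjusted p of these 7 lists was 0.609 or 0.774. With a separate flow effect in each format, chosen after seeing the data, the tubulin list was no longer called (camera BH-adjusted p = 0.0642) and the interferon list was (median -0.22, 0.0326, adjusted p = 0.822 with an estimated correlation). Without the physiologic single-table control camera no longer called the inflammatory (BH-adjusted p = 0.314), arterial (0.970), fibroblast (0.416) and tubulin lists (0.554). Without the altered one it no longer called the p53 (0.0688), ATF4 and amino acid (0.279) and ribosomal protein lists (0.596). Without physiologic rapamycin p53 (0.105), tubulin (0.0639) and cholesterol lists (0.571) lost their call, and without altered rapamycin the arterial (0.149) and tubulin lists (0.146).

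Paclitaxel raised tubulin genes, which encode its target protein. Their median was 1.09 over 12 genes (camera BH-adjusted p = 2.63e-09, adjusted p = 0.632 with an estimated correlation, 0 called over all genes and 6 higher adjusted over the list alone). TUBA1B stood at 1.26 ± 0.18, TUBB2A at 1.54 ± 0.23, TUBB at 1.26 ± 0.23 and TUBB4B at 1.02 ± 0.22 (SE, n = 2 libraries against 2). ATF4 and amino acid genes rose by a median of 0.70 over 32 genes (camera BH-adjusted p = 4.43e-13, adjusted p = 0.632 with an estimated correlation, 8 higher adjusted over the list alone). Among them were PSAT1 (2.07 ± 0.34), the folate enzymes ALDH1L2 (2.70 ± 0.33) and MTHFD2 (1.08 ± 0.23) and the pseudokinase TRIB3 (0.85 ± 0.19). Cholesterol and fatty acid synthesis genes rose by a median of 0.62, with 28 of 29 positive (camera BH-adjusted p = 1.63e-09, adjusted p = 0.632 with an estimated correlation, 1 higher adjusted over the list alone). Among them were the desaturase SCD (1.14 ± 0.21), INSIG1 (0.99 ± 0.26) and HMGCS1 (0.91 ± 0.27). G2/M genes fell, with a median of -1.36 over 50 genes (camera BH-adjusted p = 5.67e-10, adjusted p = 0.632 with an estimated correlation). This fall lay mainly in the altered pair. With no test, the G2/M median was -1.45 under altered flow (4 of 28 genes positive) and -0.17 under physiologic flow (6 of 17 positive). G1/S genes fell too, with a median of -0.50 over 42 genes, or -0.48 with the gene at 0 in a group set to its bound of 3 counts over the group (camera BH-adjusted p = 1.94e-07, adjusted p = 0.632 with an estimated correlation). The spindle genes TPX2 and KIF23 stood at -1.70 ± 0.44 and -1.69 ± 0.46 and the helicase HELLS at -1.21 ± 0.32, and 0 genes of either list passed adjusted over the list alone. With a separate flow effect in each format, chosen after seeing the data, 10 tubulins, 21 ATF4 and amino acid genes and 20 cholesterol synthesis genes were higher adjusted over the list alone, and 23 G2/M genes were lower and 1 higher.

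No single gene of 12596 passed for paclitaxel (edgeR, 0 genes, 597 at an unadjusted p below 0.05 where chance gives 629.8), and DESeq2 called 27 (15 higher, 12 lower). On the negative side, none past the edgeR test, stood STC1 (-1.69 ± 0.26), the apelin peptide gene APLN (-1.17 ± 0.18), GGT5 (-2.81 ± 0.45), PLVAP, of the diaphragms of fenestrae and caveolae (-1.63 ± 0.28), ALDH3A1 (-2.31 ± 0.42), SPOCK1 (-1.24 ± 0.23), FAR2 (-0.97), PTPRE (-0.78), CLDN11 (-0.89) and EFEMP1 (-0.87). On the positive side LARP1B (0.84), NMT2 (0.84), HABP4 (0.84) and CXCL8 (1.46 ± 0.31) were also among the genes with the smallest p. The edgeR BH-adjusted p of the genes named for paclitaxel was 0.945 or 0.995.

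Camera also called lower values with paclitaxel for endothelial identity genes (median -0.29, 20 of 24 negative, BH-adjusted p = 0.000300), interferon genes (-0.23, 0.000762) and flow-protective genes (-0.27, 17 of 19 negative, 0.0143), with NOS3 at -0.66 ± 0.18. It called higher values for NRF2 targets (0.27, 0.0108), with the ferritin chain FTL at 0.57 ± 0.21, and for mitochondrially encoded genes (0.30, 13 of 13 positive, 0.00522). Adjusted over the list alone 1 endothelial identity gene was lower and 0 members of the interferon, flow-protective, NRF2 and mitochondrial lists passed. With an estimated correlation the adjusted p of these lists lay between 0.632 and 0.911. The stress factors ATF4 (1.17 ± 0.28), VEGFA (1.17 ± 0.28) and GDF15 (0.76 ± 0.19) belong to lists that camera did not call. Without physiologic paclitaxel 5 lists were called instead of 10, with the flow-protective (camera BH-adjusted p = 0.951), NRF2 (0.312), endothelial identity (0.701), cholesterol (0.377) and interferon lists (0.831) lost. Without the altered control the flow-protective (0.364), NRF2 (0.101), G1/S (0.101) and G2/M lists (0.465) were lost. Without the physiologic control the NRF2 (0.0580), interferon (0.0580) and mitochondrial lists (0.259) were lost, and without altered paclitaxel the G1/S (0.332) and mitochondrial lists (0.981).

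The difference of the drug effects, each taken within its own format, asked where rapamycin and paclitaxel act unlike each other. ATF4 and amino acid genes were lower with rapamycin than with paclitaxel by a median of -0.91, with 31 of 32 negative (camera BH-adjusted p = 1.21e-16, adjusted p = 0.465 with an estimated correlation, 10 lower adjusted over the list alone). Cholesterol synthesis genes were lower by a median of -0.97, with 29 of 29 negative (camera BH-adjusted p = 8.79e-15, adjusted p = 0.487 with an estimated correlation, 1 lower adjusted over the list alone). With a separate flow effect in each format, chosen after seeing the data, 14 and 19 members of these lists were lower adjusted over the list alone. PSAT1 stood at -3.86 ± 0.49, ALDH1L2 at -3.03 ± 0.42, SCD at -1.51 ± 0.30, CXCL8 at -2.33 ± 0.44 and RBM24 at -2.69 ± 0.54. STC1 (2.93 ± 0.32), GGT5 (3.45 ± 0.51), SPOCK1 (1.70), ITPR3 (1.01) and RIN1 (1.51) lay on the other side. No gene of 12596 passed (edgeR, 0 genes, smallest BH-adjusted p = 0.559), and DESeq2 called 10. An unadjusted edgeR p below 0.05 was found for 387, where chance gives 629.8. The fit with a flow effect per format called 1 gene with edgeR, STC1 (3.02 ± 0.27, BH-adjusted p = 0.0263), and camera also called lower values with rapamycin for the arterial list (median -0.31, BH-adjusted p = 0.0338, adjusted p = 0.603 with an estimated correlation). Each drug was deposited in 1 format only, so this difference cannot be taken within a format.

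Of the other lists in the drug difference, camera called lower values with rapamycin for ER stress (median -0.43, BH-adjusted p = 1.07e-07), tubulins (-0.62, 1.9e-05), fibroblast markers (-1.66, 4.73e-05), low-flow inflammatory genes (-0.26, 0.000445), mitochondrially encoded genes (-0.37, 0.00609), p53 targets (-0.21, 0.0220) and NRF2 targets (-0.14, 0.0331). The fibroblast list again rested on 5 tested genes. Camera called higher values for ribosomal proteins (0.26, 0.000248), translation factors (0.34, 0.000417), G1/S genes (0.42, 0.00124) and endothelial identity genes (0.29, 0.00555). G2/M genes, lower as a list with each drug over both flows but with paclitaxel mainly under altered flow, were not called (0.41, 0.408). With an estimated correlation the adjusted p of the called lists lay between 0.465 and 0.802. Adjusted over the list alone 1 inflammatory gene and 2 tubulins were lower and 0 members of the other 9 lists passed. In fits that left out 1 library the ER stress, tubulin, inflammatory, ATF4 and cholesterol lists were called each time, and the number of called lists lay between 9 and 14. The NRF2 list was lost without the sparse-matrix physiologic (BH-adjusted p = 0.0858) or altered control (0.210), the altered single-table control (0.316), physiologic rapamycin (0.104) or physiologic paclitaxel (0.388). The endothelial identity list was lost without the sparse-matrix physiologic control (0.0596), the altered single-table control (0.187), physiologic rapamycin (0.204) or physiologic paclitaxel (0.865). The p53, ribosomal protein and translation lists were lost without the altered single-table (0.126, 0.785 and 0.126) or sparse-matrix control (0.210, 0.827 and 0.161). The p53 and ribosomal protein lists were also lost without physiologic rapamycin (0.204 and 0.0820) or physiologic paclitaxel (0.291 and 0.125). The G1/S list was lost without the altered sparse-matrix control (0.862) or altered paclitaxel (0.797). The fibroblast list was lost without the physiologic single-table control (0.125), and the mitochondrial list without either physiologic control (0.249 and 0.206), altered rapamycin (0.559) or altered paclitaxel (0.797).

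Whether a drug effect differs between flows was tested by interaction terms. Each is measured against a flow effect pooled over the controls of both formats and the other drug, although 1186 genes differed in flow effect between formats, so the interactions of the drugs can partly mirror each other. For rapamycin the smallest p belonged to HES4 (2.88 ± 0.77), SMAD7 (1.31), MICOS10 (0.95) and the heat shock gene HSPA1A (1.2) on the positive side, with RNASE4, which had 0 counts in physiologic rapamycin and gets no fold. On the negative side were ABI3BP (-2.16 ± 0.56), GALNT15 (-3.75 ± 1.09), RPS27 (-1.16) and PDE2A (-1.40). No gene of 12965 passed (edgeR, 0 genes, smallest BH-adjusted p = 1.00), and DESeq2 called 0. An unadjusted edgeR p below 0.05 was found for 67, where chance gives 648.25, so the absence of calls is no evidence against an interaction. Cholesterol synthesis genes had a positive interaction in 28 of 29 cases (median 0.60, camera BH-adjusted p = 3.23e-07, adjusted p = 0.891 with an estimated correlation, 0 adjusted over the list alone). Beside the G2/M list, camera also called negative rapamycin interactions for mitochondrially encoded (median -0.47, 13 of 13 negative, BH-adjusted p = 0.000707), ribosomal protein (-0.29, 65 of 83, 0.00207) and endothelial identity genes (-0.21, 19 of 24, 0.00966) and a positive one for BMP and Notch targets (0.43, 8 of 10, 0.00801). Their adjusted p was 0.891 with an estimated correlation, and 0 members passed adjusted over the list alone. For the flow by rapamycin interaction edgeR called 8 genes with a separate flow effect in each format, chosen after seeing the data. Without 1 of the single-table controls the interaction sets rapamycin against sparse-matrix pairs only, so drug and format cannot be told apart. For paclitaxel the smallest p belonged to APOLD1 (3.56 ± 0.33), an immediate early gene of endothelium (edgeR BH-adjusted p = 0.482), the transcriptional repressor BCL6B (1.86 ± 0.25), the protease ADAMTS1 (2.56 ± 0.35), GPR162 (3.52 ± 0.59) and CGNL1 (1.55 ± 0.27). On the negative side were SEMA3C (-4.48 ± 0.56), KRT7 (-3.69 ± 0.52), ANGPT2 (-3.48 ± 0.50) and the activin subunit INHBA (-5.25 ± 0.76). Here cholesterol synthesis genes had a negative interaction in 28 of 29 cases (median -0.83, camera BH-adjusted p = 1.26e-09, adjusted p = 0.567 with an estimated correlation, 16 lower adjusted over the list alone). Beside the cell cycle lists, camera also called negative paclitaxel interactions for ATF4 and amino acid genes (29 of 32 negative, BH-adjusted p = 1.99e-05), metallothioneins (5 of 5, 0.00165), ER stress (17 of 20, 0.00698), glycolysis and hypoxia (22 of 28, 0.0189) and smooth muscle markers (5 of 6, 0.0488). It called positive ones for endothelial identity (23 of 24 positive, 0.000725), mitochondrially encoded (13 of 13, 0.000777), interferon (22 of 25, 0.00204), flow-protective (17 of 19, 0.00817) and arterial genes (13 of 17, 0.0261). With an estimated correlation the adjusted p of these 10 lists lay between 0.567 and 0.878. Adjusted over the list alone 1 ATF4 and amino acid gene and 2 metallothioneins were lower, 1 flow-protective gene was higher and 0 members of the others passed. Within a format, 1 library against 1, the cholesterol median moved from -0.65 under physiologic to -0.25 under altered flow with rapamycin and from 0.89 to 0.09 with paclitaxel. For the paclitaxel interaction none of 12965 genes passed (edgeR, 0 genes, 1189 at an unadjusted p below 0.05 where chance gives 648.25), and DESeq2 called 32. The edgeR test called 19 genes for the flow by paclitaxel interaction with a separate flow effect in each format. Without 1 of the sparse-matrix controls this interaction sets paclitaxel against single-table pairs only, and drug and format again cannot be told apart.

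Under each flow, 1 drug library was set beside 1 control library of its format, with no replicate and no test. Under physiologic flow FABP4, a fatty acid carrier of capillary and venous endothelium, stood at 2.43 CPM (95% interval 1.83 to 3.17) with rapamycin and 53.1 (49.9 to 56.5) in the control, DKK2, a Wnt antagonist, at 6.70 and 117, and the arterial connexin GJA4 at 47.3 and 784. APLNR and HSPA2 had ratios of 0.0757 and 0.0790. GALNT15 was at 17.5 CPM with rapamycin and 1.71 in the control, and LMOD3, FST, CPNE7 and CDCP1 had ratios of 7.80, 7.70, 6.12 and 5.83. Against the other physiologic control the log2 ratios of CDCP1, FABP4, DKK2, GJA4, APLNR and HSPA2 had the opposite sign. Under altered flow the mitotic kinase PLK1 stood at 1.93 CPM (1.36 to 2.66) with rapamycin and 14.0 (12.6 to 15.5) in the control. CDC20 stood at 2.82 and 17.0 and ALDH1A1 at 3.91 and 32.5, while LMO7 stood at 53.4 and 15.4 and the prostaglandin synthase PTGDS at 9.91 and 2.42. IL1A and TROAP had ratios of 0.136 and 0.140, and ENKUR, PIM1 and FCGR2A of 4.80, 4.04 and 3.58. Against the other altered control the log2 ratio of IL1A had the opposite sign.

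With paclitaxel under physiologic flow the asparagine synthetase ASNS stood at 42.5 CPM (36.2 to 49.6) against 6.34 (4.55 to 8.60) in the control, PSAT1 at 86.8 and 13.0 and the stress factor ATF3 at 57.4 and 11.6. NIBAN1 and the protease MMP10 had ratios of 5.80 and 5.61. IGFBP5 was at 32.1 and 313 CPM, ALDH3A1 at 8.08 and 69.3, and SLCO2A1, AQP3 and ADAM19 had ratios of 0.132, 0.167 and 0.193. Under altered flow TUBA1A stood at 2698 CPM with paclitaxel and 879 in the control, TUBA4A at 180.3 and 46.9, TUBB2A at 219 and 64.8, CXCL8 at 88.0 and 25.4 and APOLD1 at 28.7 and 7.26, with the opposite sign for APOLD1 against the other altered control. The mitotic genes NCAPG (3.0 and 43.0 CPM), ANLN (6.56 and 89.1), DLGAP5 (ratio 0.0932) and CDK1 (3.82 and 36.3) and the guidance factor SEMA3C (ratio 0.0730) lay lower with paclitaxel.

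**Figure D2:**
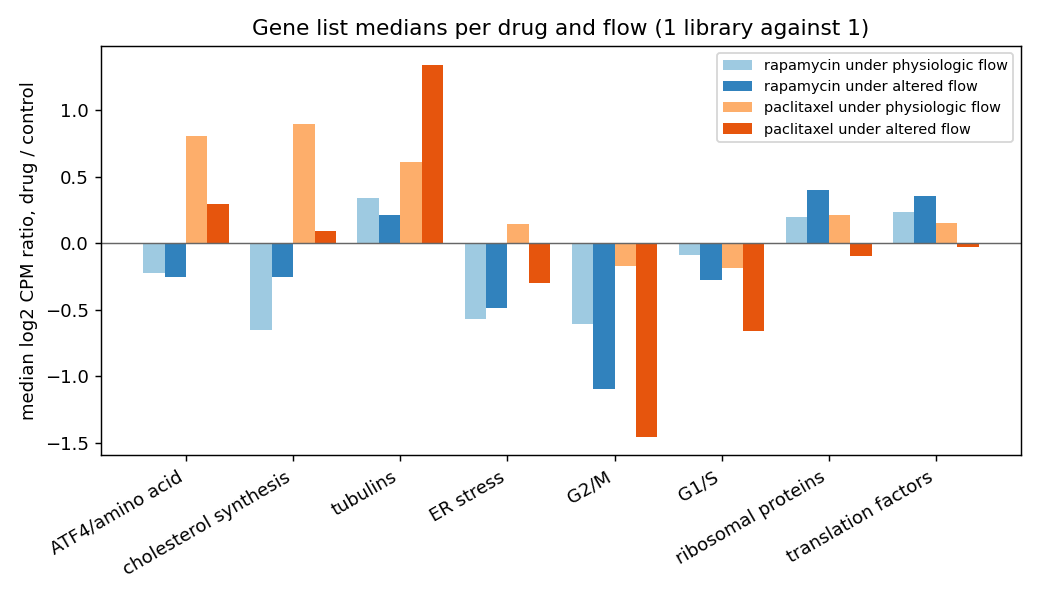
Median log2 CPM ratio (drug over the control of the same format) of 8 gene lists for each drug and flow, 1 library against 1. Bars for tubulins reach 1.34 with paclitaxel under altered flow, and bars for cholesterol synthesis stand at -0.65 with rapamycin and 0.89 with paclitaxel under physiologic flow.

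As a description of these pairs, the tubulin median was 0.61 with paclitaxel under physiologic and 1.34 under altered flow, and the ATF4 and amino acid median 0.81 and 0.30, each above all 10000 random lists matched on expression. The cholesterol synthesis median with paclitaxel was 0.89, above all of its random lists, and 0.09 (percentile 87.8), and the G2/M median -0.17 (percentile 2.89) and -1.45 (percentile 0.0). With rapamycin the G2/M median was -0.61 and -1.09 and the ER stress median -0.57 and -0.49 under physiologic and altered flow, each at percentile 0.0. Across the 7356 genes of the correlation, which are not independent replicates, the drug changes under the 2 flows had Pearson r = 0.604 (Spearman 0.573) for rapamycin and 0.123 (0.146) for paclitaxel. The paclitaxel pairs held fewer counts and cells, and counting noise lowers a correlation, so these values do not compare the drugs. The median size of the log2 ratio over genes, a summary chosen after seeing the data, was 0.220 and 0.176 for rapamycin and 0.200 and 0.213 for paclitaxel.

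Cells with at least 2 of 10 cycling markers, such as MKI67 and TOP2A, made up 1.71% (95% interval 1.2 to 2.35, 36 of 2110 cells) of the physiologic and 4.81% (4.11 to 5.59, 161 of 3349) of the altered single-table control when each cell was thinned to 1000 counts. With rapamycin the shares were 0.471% (0.274 to 0.752, 17 of 3613) and 2.93% (2.24 to 3.75, 60 of 2050). In the sparse-matrix controls 2 of 846 cells (0.236%, 0.0286 to 0.851) and 6 of 153 (3.92%, 1.45 to 8.34) passed, and with paclitaxel 3 of 399 (0.752%, 0.155 to 2.18) and 2 of 229 (0.873%, 0.106 to 3.12). The unthinned shares were 5.73%, 10.9%, 2.69% and 5.70% in the single-table controls and rapamycin libraries and 5.08%, 15.7%, 3.76% and 6.11% in the sparse-matrix controls and paclitaxel libraries, each physiologic before altered. Thinning left out 1277, 1629, 1482 and 1335 cells of the single tables as too shallow and 0 of the sparse matrices. These intervals cover counting error only, each share belongs to 1 library, and no test between libraries was made. No cell type that should lack these markers was present to give their background from free RNA.

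**Figure D3:**
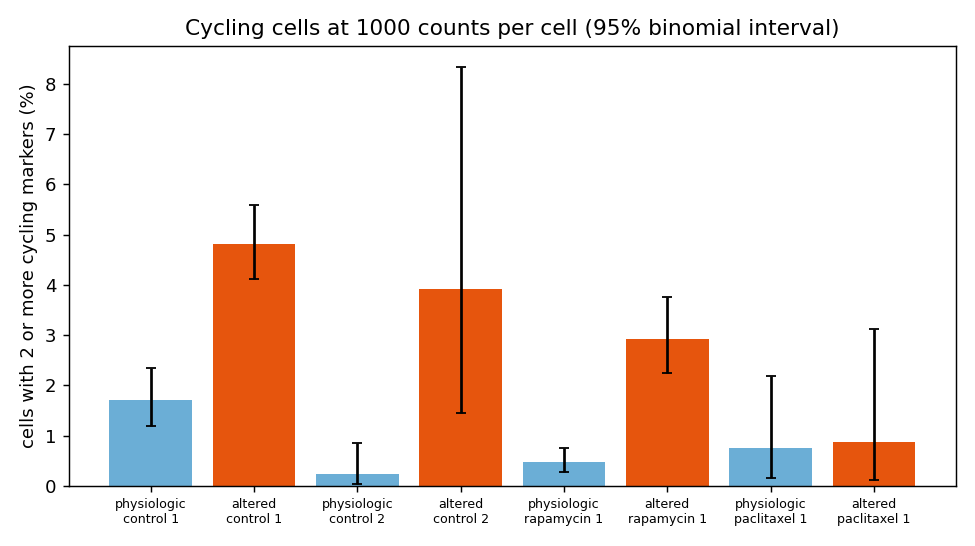
Share of cells (%) with at least 2 cycling markers after thinning to 1000 counts per cell, 1 bar per library, with exact binomial 95% intervals. The share is 4.81% in the altered and 1.71% in the physiologic single-table control, and the intervals of the paclitaxel libraries (0.752% and 0.873%) overlap.

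At least 2 of 9 endothelial markers, such as PECAM1 and CDH5, were seen in 86.9% and 87.7% of thinned cells of the physiologic and altered single-table controls, 82.9% and 80.7% with rapamycin, 79.0% and 85% in the sparse-matrix controls and 65.9% and 84.7% with paclitaxel. Unthinned, the shares were 86.1%, 88.2%, 87.8% and 81.2% in the single tables and 99.2%, 98.7% and 99.1% in the sparse-matrix controls and altered paclitaxel, and every physiologic paclitaxel cell passed. VWF, the carrier protein of coagulation factor VIII and 1 of the markers, stood at 46.8 and 35.5 CPM in the physiologic sparse-matrix control and paclitaxel libraries and at 440.4 CPM or more in the other 6. After thinning, 1 of 3349 cells of the altered single-table control (0.0299%) had 2 fibroblast markers and 1 of 3613 cells of physiologic rapamycin (0.0277%) had 2 leukocyte markers. In every other library and class 0 cells had 2 smooth muscle, fibroblast or leukocyte markers, which limits cells with 2 such markers seen in 1000 counts and not the share of these cell types, whose detection at this depth is unknown. Unthinned, the highest shares of a library were 1.96% for smooth muscle, 0.654% for fibroblast and 0.266% for leukocyte markers. Within each format 1 cluster was cycling-like, with 458 of 16845 cells in the single tables and 43 of 1627 in the sparse matrices. Several other clusters were led by genes also named for flow or drug, such as PI16, STC1 and BMP4, and the sizes of the other clusters were not compared between groups. A single-table cluster of 261 cells led by TAGLN together with replication genes was not counted as cycling-like. A single-table cluster of 439 cells had a median of 10.6 times the count of their own libraries, was led by CCNA1, MT2A and IL1RL1, and was left in, with no doublet caller run.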

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

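The depth and drug tests of the first pattern were set before their own results were seen, and the other tests in this part, including the fit of a flow by format difference itself, were chosen only after the results were seen.

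The flow effect differed between the 2 deposit formats for 1186 of 12596 genes in a test of the difference itself (edgeR, BH-adjusted p below 0.05, 3314 at an unadjusted p below 0.05), 375 higher in the single tables and 811 higher in the sparse matrices. Among those singled out after their values were seen, VWF, the large adhesive protein of endothelial storage granules, differed by -4.34 ± 0.20 (single-table minus sparse-matrix format, log2), with flow changes of 0.15 and 4.52. CD34, a sialomucin of endothelial and progenitor cells, differed by -4.32 ± 0.29, falling under altered flow in the single tables (-2.11) and lying higher in the sparse matrices (2.25). EXOC4, a subunit of the exocyst, differed by -4.28 ± 0.23, the phospholipase PLCB1 by -3.59 ± 0.23 and the calcium-binding MCTP1 by -3.09 ± 0.21. Camera called 8 lists for this difference. Flow changes were lower in the single tables for ribosomal proteins (median -0.61, camera BH-adjusted p = 9.22e-11), mitochondrially encoded genes (-0.59, 0.000727), endothelial identity (-0.39, 0.00726), flow-protective genes (-0.79, 0.00845), arterial genes (-1.01, 0.00937) and nuclear oxidative phosphorylation (-0.27, 0.0218). They were higher there for cholesterol synthesis (0.52, 0.00205) and glycolysis and hypoxia (0.48, 0.00205). None of the 8 was called with an estimated correlation, at adjusted p of 0.725 for cholesterol synthesis, 0.770 for oxidative phosphorylation and 0.682 for each of the other 6.

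Each drug was deposited in 1 format, so a drug that changes the response to flow could enter this difference. For the called genes the format difference in the controls alone had a median of 0.929 times the fitted one (quartiles 0.793 and 1.07). It was thus also present in these genes without a drug. But the residual spread of the fit is the disagreement of control and drug pairs, so it calls genes whose pairs agree. A ratio near 1 was therefore favoured in advance and cannot decide on the drugs, which stay open as a source. For depth, cells of at least 2000 counts were kept and every library was thinned to 1 total. The difference of the called genes then had a median of 1.00 times its former size (quartiles 0.942 and 1.06). Of the 865 genes then called, 826 were among the 1186. Cells below 2000 counts, which only the single tables held, are thus argued against as the whole source. Thinning of summed counts keeps each gene's expected share and does not equate counts per cell, so depth and counts per cell otherwise stay open. The 811 genes higher in the sparse matrices had a median genomic span of 108.6 kb, 3.27 times that of unchanged genes matched on expression (33.2 kb, 29.8 to 36.6 in 95% of the random sets), while the 375 genes higher in the single tables had 25.3 kb against 34.3. Gene length therefore stays open, and a differing share of unspliced or nuclear RNA may contribute: from physiologic to altered flow, genes with a span of at least 100 kb went from 17.3% to 20.2% of the counts with paclitaxel and from 19.9% to 18.7% with rapamycin, but only from 18.1% to 19.0% in the sparse-matrix and 19.2% to 18.6% in the single-table controls.

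The lower ATF4 and amino acid and cholesterol synthesis values with rapamycin than with paclitaxel form the second pattern. With all libraries thinned to 1 total the median difference of the amino acid list was -0.92 (-0.91 before). That of the cholesterol list was -1.05 (-0.97 before). Thinning of summed counts keeps each gene's expected share, so it bears on counting noise only, and depth stays open. A single flow or library as the whole source is argued against, because the median differences were -1.03 and -1.55 under physiologic and -0.55 and -0.34 under altered flow. The drugs, which the design names, stay open as a source and were not tested apart from the format. A format that registers drug responses differently could give the same pattern, and the explanations cannot be told apart because 0 drugs were deposited in both formats.

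The third pattern is the 509 genes of the flow effect over 8 libraries. Of the 32 splits of the 8 libraries that could be fitted, 3 gave as many genes, the real split included. The other 2 called 899 genes each and part the second control pair and the paclitaxel pair by flow. They leave the other pairs together, which the condition terms absorb, so they are the same fit with the sides exchanged. Other splits that leave pairs together are mirrored in this way too, so the 32 are not all distinct. The fit with 899 genes follows flow within the sparse-matrix format. The splits that part the single-table pairs by flow in the same way called 0 genes. Fits of 1 format alone called 2053 genes in the sparse matrices and 2068 in the single tables. The count of splits thus cannot decide on a grouping by chance, which is not excluded. Among the 8 splits that part all 4 conditions as the real one does, the other 7 called 0 genes at most, and these are too few for a share under 0.05.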

How the results depend on the processing

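The tests with a separate flow effect per format and with at least 2000 counts per cell, and the median size of the log2 ratio as a summary, were chosen only after the data were seen. The other alternatives were fixed before the data were examined.

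The flow effect over 8 libraries called 492 to 523 genes with DESeq2 size factors, all barcodes, stricter or deeper cells, equal totals, or without mitochondrial and ribosomal protein genes. DESeq2 called 1358 (501 shared with the 509), no gene filter 837 (509 shared), the single tables alone 2068, the sparse matrices alone 2053, no format term 4 and a separate flow effect per format 3009. Leaving out each library gave 44 to 537, and of the genes named for flow 54 were no longer past the threshold without a format term and 11 to 49 without a library. The causes were not tested, except that fits of 1 format or without a library hold fewer samples.

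For the rapamycin effect over 8 libraries, the paclitaxel effect over 8 libraries and the rapamycin minus paclitaxel effect, where edgeR called 0, DESeq2 called 35, 27 and 10. Without a gene filter CYP1B1 was called for rapamycin (1 gene), PSAT1 and STC1 for the difference (2 genes) and APOLD1 for the flow by paclitaxel interaction (1 gene). A separate flow effect per format called 89 for rapamycin and 1 for the difference. Leaving out each library gave 0 to 0 for these and for the flow effect in control libraries. The latter had 86 with DESeq2, 21 without a gene filter and 2 with the replicate block, which changed no other call because it was fitted there alone. The flow by paclitaxel interaction had 32 with DESeq2, 19 with a separate flow effect per format and 0 to 1451 without a library, and the flow by rapamycin interaction 8 and 0 to 374 for the last 2 of these.

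Camera with an estimated correlation called 0 lists for flow, rapamycin, paclitaxel and the drug difference, and fry 1, 0, 0 and 0. Leaving out each library gave 13 to 18, 9 to 12, 5 to 10 and 9 to 14 lists.

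In the drug effect within each flow, the other control replicate crosses formats by construction. The median size of the log2 ratio was then 0.509 and 0.394 for rapamycin and 0.523 and 0.476 for paclitaxel under physiologic and altered flow. Ratios turned to -1.10 for CDCP1, 2.16 for FABP4, 1.28 for DKK2, 6.19 for GJA4, 0.93 for APLNR, 0.15 for HSPA2, 0.39 for IL1A and -1.02 for APOLD1, and 24 other named ratios moved without changing sign.

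Unthinned endothelial shares were 99.2%, 98.7%, 87.8%, 100% and 99.1% in the second physiologic and altered controls, physiologic rapamycin and physiologic and altered paclitaxel. Unthinned cycling shares were 5.73%, 5.08%, 10.9%, 15.7%, 2.69%, 5.70%, 3.76% and 6.11% in the first and second physiologic controls, the first and second altered controls, and the rapamycin and paclitaxel libraries. The highest unthinned smooth muscle, fibroblast and leukocyte shares of a library were 1.96%, 0.654% and 0.266%. At resolution 1 the cycling-like clusters held 1.76% of single-table and 0.860% of sparse-matrix cells, against 2.72% and 2.64%. Counts per cell limit the shares, since the thinned cells keep 1000 counts of a median of up to 12629.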

Other observations

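The values in this part were looked at only after the main results were seen, and no tests were made of them.

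Genes of the metallothionein list, which bind or export zinc, had median log2 CPM ratios of altered over physiologic flow of 1.17 in the single-table controls and 0.88 with rapamycin, and of -0.07 in the sparse-matrix controls and -0.56 with paclitaxel. Each is a median over 3 genes in 1 library against 1. Among matched random lists these stood at percentiles 99.9, 99.8, 55.7 and 8.22. Interferon genes had medians of -0.69 and -0.21 in the single-table control and rapamycin pairs (percentiles 0.0 and 0.1). In the sparse-matrix control and paclitaxel pairs the medians were -0.25 and -0.17, but at percentiles 15.2 and 35.9, within the range of random lists. The median of secreted senescence genes was -1.31 over 17 genes with paclitaxel, with 14 of them negative, and between -0.33 and 0.04 in the other pairs. Glycolysis and hypoxia genes had medians of 0.17 and 0.05 in the single-table control and rapamycin pairs (percentiles 97.1 and 49.2). The medians were -0.44 and -0.59 in the sparse-matrix control and paclitaxel pairs (percentiles 0.4 and 0.0). Immediate early and heat shock genes stood at -0.33 with rapamycin under physiologic flow (17 of 21 genes negative) and at 0.27 under altered flow (18 of 21 positive).

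A cluster of 261 single-table cells was led by the contractile and matrix genes TAGLN, TGFBI and MYL9 together with the replication genes TK1, PCLAF and RRM2, and it rests on no fixed marker set, so it stays unnamed. Clusters of 4676 and 4095 single-table cells had medians of 0.565 and 0.517 times the count of their own libraries and were led by MTRNR2L12, MTRNR2L8 and MTRNR2L1 and by FCGR2A, TAOK1 and OAS3. The first principal component of log2 CPM took 63.8% of the variance and placed all 4 single-table libraries below 0 and all 4 sparse-matrix libraries above it. The second took 20.5% and placed the altered libraries above 0 and the physiologic ones below it in both formats.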
